A study of Mus musculus with 2 samples.

How the data were processed

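Single-cell RNA was measured in 2 libraries of mouse liver cells, each from 1 tumour-bearing mouse with floxed alleles of Glul, the gene for glutamine synthetase (GS). The control mouse received AAV8-GFP and the GS-KO mouse received AAV8-Cre, both as virus 7 weeks before collection. AAV8 is a viral vector that delivers genes mainly to hepatocytes, and Cre removes the floxed part of the gene. Cells came from the supernatant of the low-speed spin after collagenase perfusion, were enriched with magnetic beads for F4/80, a surface protein of macrophages, and were passed through dead cell removal. A droplet 3′ kit was used, so each transcript was counted near its 3′ end. The labels name the chemistry 3PrimeV2 and in 1 place call the assay single-nucleus, and which applies was not settled here.

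Per the submitters' processing notes, the authors ran Cell Ranger with the mm10 mouse genome and deposited a count matrix per library, whose values are raw UMI counts per gene and barcode. UMIs are molecular identifiers that let PCR copies of a transcript count once. The matrix header carried software version 3.1.0. Each matrix listed 32285 genes, and no barcode had under 500 UMIs, so barcodes below that level were already absent. Whether all barcodes left held cells was not tested. Gene positions were taken from GENCODE M21 on GRCm38, which held 32158 of the gene identifiers.

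The control library held 5074 barcodes and 64770011 UMIs, and the GS-KO library 1366 barcodes and 8805330 UMIs. A barcode was kept with at least 500 UMIs, at least 200 genes and at most 20% mitochondrial UMIs, which 3275 control and 662 GS-KO barcodes met. Scrublet, run per library with an expected rate of 5%, then called 24 control and 7 GS-KO doublets, which were removed. The 3251 control and 655 GS-KO cells left were clustered together: normalisation to 10000 UMIs, log transform, 2000 variable genes among those in at least 5 cells, 30 principal components, 15 neighbours and Leiden clustering at resolution 1 with seed 1. No batch correction was applied, since batch and group coincide. The tools were Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.

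The 18 clusters were named from marker genes of 20 cell classes. A marker counted when its CPM (UMIs scaled to a fixed total per cluster) in the cluster was at least 2 times that in all other cells, with 10 CPM added to both, and at least 20% of the cluster's cells had a UMI of it. A name needed at least 3 such markers, more than any other class, and no other class with more markers among the 10 leading genes; a cluster with none of its own there needed 5. Names end in "-like" because they rest on RNA alone. Clusters 2 and 16 stayed unnamed, cluster 2 because the Kupffer and macrophage markers tied.

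UMIs were summed per class and library and scaled to CPM, the count of a gene per 1000000 UMIs of the sum. Shares carry exact binomial (Clopper-Pearson) 95% intervals, CPM values exact Poisson 95% intervals, and CPM ratios a 95% interval from the conditional binomial. With 1 mouse per group no test of a group difference exists. The intervals cover counting error only, not differences between mice, between cells of a mouse or between preparations. Kupffer-like, macrophage-like and monocyte-like cells were compared, and every other class with at least 30 cells in each library. Where the GS-KO library had 0 UMIs of a gene, the fold was computed against 3 counts and is a lower bound for counting error only.

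For 31 gene lists, the log2 ratio of GS-KO over control CPM was taken for each member with at least 20 UMIs over both libraries in the class, with a prior count of 0.5 on average, and the median over at least 3 members was reported. Its 95% interval comes from 1000 Poisson draws around the counts. Its percentile is among 10000 random lists of equal size, matched on expression in 20 bins, and describes these libraries only. Members at least 1.5-fold higher or lower were counted. Detection was compared after thinning each cell to 1000 UMIs, which left 3054 control and 599 GS-KO cells and left out 197 and 56 shallower ones.

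Genes were named by a rule: among genes with at least 50 UMIs in a class and a CPM ratio of at least 2 either way, the 12 higher and the 12 lower in the GS-KO library by the interval bound nearest 1 in the Kupffer-like, macrophage-like and monocyte-like classes, and 5 each way in the others. Mitochondrial, ribosomal protein, haemoglobin, immunoglobulin, sex-linked and hepatocyte list genes were left out of the ranking, as were genes more than 5 times higher in another class. Glul was named besides, and from each list the members with most UMIs or the interval bound farthest from 1. Other genes were chosen after their values were seen and are so marked. The cell filter, markers, gene lists, classes, naming rule and most alternatives were chosen before the data were examined.

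The alternatives were other limits on mitochondrial share and UMIs, keeping called doublets, Leiden resolutions 0.5 and 2, clustering of cells thinned to 1000 UMIs, median-of-ratios scaling, a total without mitochondrial, ribosomal, haemoglobin and hepatocyte genes, other minimum counts for list members, the mean over cells, and thinning before summing. Added after the data were seen were values without single GS-KO cells, per cluster, with macrophage clusters weighted equally, with clusters 1, 2, 3, 6 and 11 summed, and, for shares, with mitochondrial limits of 50% and 80%. Median-of-ratios scaling moved log2 ratios by at most 0.08 in the 4 classes where it was run. The median log2 ratio of all genes with at least 50 UMIs was −0.12 in Kupffer-like, −0.18 in B-like and −0.23 in T-like cells, and within 0.1 of 0 in the other classes.

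The intervals were checked on simulated Poisson counts drawn at the depth of each class. The intervals assume such counts, so the check covers counting error and leaves out the spread between cells. In macrophage-like cells, 96.3% of intervals of unchanged genes covered a ratio of 1, and 71.7% and 91.8% of intervals left out 1 for genes set 2-fold and 4-fold apart. For the 10 GS-KO Kupffer-like cells, the last shares were 37.9% and 74.7%. A list of 30 genes set 1.5-fold apart reached percentile 100 in each of the 4 classes tested. A list of 30 unchanged genes lay at percentile 87 in Kupffer-like and 53.25 in hepatocyte-like cells, with the other classes between.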

Results

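Glul is the gene for glutamine synthetase, which makes glutamine from glutamate and ammonia. It was targeted by Cre in 1 of the 2 mice whose liver cells were compared, both with β-catenin-mutant liver tumours. The control library (AAV8-GFP, 1 mouse) gave 5074 barcodes with 64770011 UMIs, and the GS-KO library (AAV8-Cre, 1 mouse) gave 1366 barcodes with 8805330 UMIs. The submitters' text states a target of at least 7500 cells at 20000 reads per cell, while 3251 control and 655 GS-KO cells were kept. Mitochondrial RNA, whose share rises in damaged cells, made up more than 20% of UMIs in 35.5% (95% interval 34.1 to 36.8) of control and 50.8% (48.1 to 53.5) of GS-KO barcodes. Kept cells had a median of 7320 UMIs in the control and 4104 in the GS-KO library, and hepatocyte-like cells differed most in depth, with 13639 against 2686.5. No replicate exists, so no difference can be set against the spread between mice, and all intervals cover counting error only.

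The comparison of Glul asked in which cells its RNA was lower after Cre. Hepatocyte-like cells had 3032 CPM of Glul (95% interval 3010 to 3054) in the control library and 125 (95.3 to 160.0) in the GS-KO library, 24.3-fold lower (19.0 to 31.8). Cluster 4, the deeply covered hepatocyte-like cells, had 3315 against 44.1 CPM of Glul (75.1-fold lower, 40.9 to 157), and cluster 5, the shallow ones, 3747 against 260.0 (14.4-fold lower, 10.9 to 19.4). Control cells had 2582 CPM in the dividing hepatocyte-like cluster 13 but 121 in the hepatocyte-like cluster 15. Tumour cells were not told apart from other hepatocytes, so a different mix of them was not separated from lower Glul within like cells. In macrophage-like cells pooled Glul was 258 and 255 CPM, a ratio of 0.986 (0.862 to 1.12; a log2 ratio of −0.31 as a mean over cells), but the ratio was 1.21 (1.02 to 1.42) in cluster 1, 0.632 (0.442 to 0.877) in cluster 6 and 0.843 (0.611 to 1.14) in cluster 11. Kupffer-like cells, named from markers of the resident macrophages of the liver, had 252 and 185 CPM, a ratio of 0.732 (0.505 to 1.03). Glul was also lower in endothelial-like cells, at 254 against 155 CPM (ratio 0.612, 0.477 to 0.782), monocyte-like cells, at 139.9 against 81.5 (0.582, 0.392 to 0.843), neutrophil-like cells, at 144 against 57.9 (0.403, 0.216 to 0.726), and B-like cells, at 72.9 against 29.6 (0.406, 0.221 to 0.695). RNA of abundant hepatocyte genes was lower in the same 4 classes, at ratios of 0.273, 0.526, 0.521 and 0.0960, so Glul RNA carried in from hepatocytes was not separated from their own. Nor was it separated in macrophage-like and Kupffer-like cells. Level pooled Glul in macrophage-like cells therefore need not mean that their own Glul was level. Glul (ENSMUSG00000026473, protein coding) lies on the plus strand of chromosome 1 at 153899944 to 153909723 of GRCm38.

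At equal depth of 1000 UMIs, Glul was detected in 72.8% (69.0 to 76.4) of control and 21.1% (11.4 to 33.9) of GS-KO hepatocyte-like cells, and without thinning in 88.1% and 42.6%. B-like cells, which serve here as a class with little Glul, had it in 7.24% and 1.69% after thinning and in 21.7% and 10.8% without, at median depths of 3668 and 3823 UMIs. Over all kept cells, Glul was 1507 CPM against 120.2. The sources used here do not give the deleted part of the gene, so a 3′ count of Glul RNA says nothing about whether the deletion took place in a given cell.

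**Figure D1:**
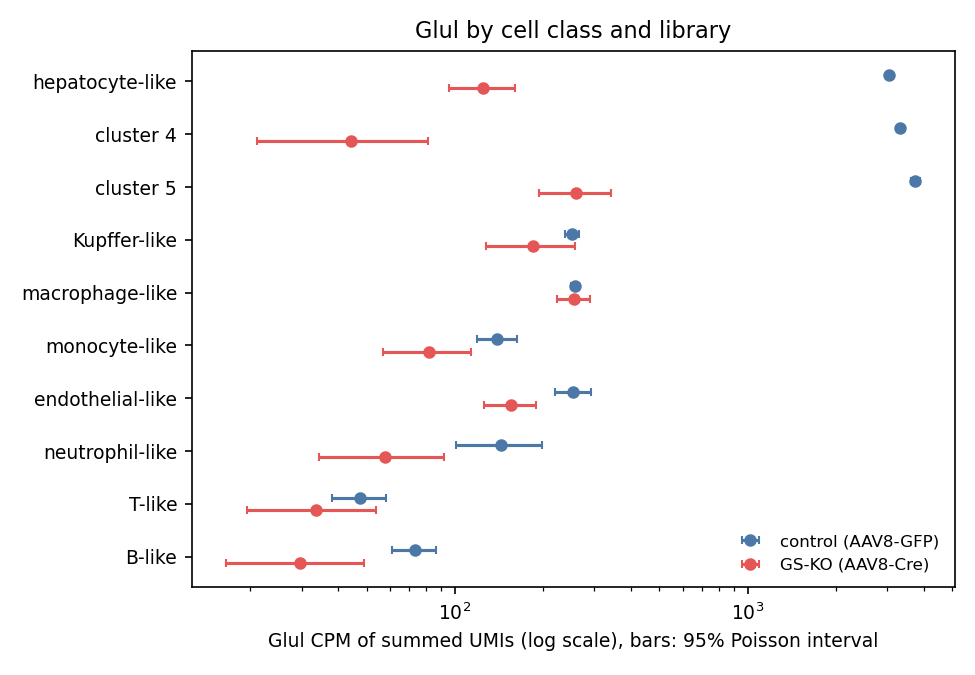
CPM of Glul (log scale) by cell class and for hepatocyte-like clusters 4 and 5, as points with 95% Poisson intervals, in the control and the GS-KO library. Hepatocyte-like cells stand apart, with 3032 against 125 CPM, while pooled macrophage-like cells have 258 and 255. Glul RNA carried in from hepatocytes was not separated.

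Macrophages were the cells the bead step was meant to enrich, and the comparison of shares asked how the captured cell classes differed. Kupffer-like and macrophage-like cells together were 33.7% (32.0 to 35.3) of control and 10.7% (8.43 to 13.3) of GS-KO cells, 1094 against 70 cells. Kupffer-like cells alone were 8.80% (7.85 to 9.82) and 1.53% (0.734 to 2.79), and macrophage-like cells 24.9% (23.4 to 26.4) and 9.16% (7.06 to 11.6). The split between these classes is not sharp, since the macrophage-like cluster 1 met 13 macrophage and 11 Kupffer markers. Macrophage-like cells are thus not a class without resident cells. The share differences, −7.27 points for Kupffer-like and −15.7 for macrophage-like cells, were −16.8 and −9.62 at Leiden resolution 0.5. Cluster 2, a shallow cluster in which both sets of markers tied, held 8.43% and 4.58%, and with it the macrophage share was 42.1% against 15.3%. Neutrophil-like cells were 3.08% (2.51 to 3.73) and 15.7% (13.02 to 18.7), endothelial-like cells 3.88% (3.24 to 4.60) and 13.4% (10.9 to 16.3), and monocyte-like cells, the blood-derived precursors of macrophages, 3.60% (2.99 to 4.30) and 8.09% (6.12 to 10.5). Hepatocyte-like cells were 20.4% (19.0 to 21.8) and 10.4% (8.15 to 12.98). Barcodes over the mitochondrial limit were rich in abundant hepatocyte genes, at 97669 and 83211 CPM of non-mitochondrial UMIs. With limits of 50% and 80%, cells named hepatocyte-like (limits chosen after the data were seen) were 15.8% against 3.65% and 19.99% against 7.34%, but a cluster led by mitochondrial genes stayed unnamed, so how far this share depends on the limit stays open.

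B-like and T-like lymphocytes differed less in share, at 14.5% (13.3 to 15.7) and 18.3% (15.4 to 21.5) for B-like and 8.24% (7.32 to 9.24) and 12.4% (9.94 to 15.1) for T-like cells. Among cells other than the macrophage-lineage clusters, neutrophil-like cells were 5.31% and 18.6%, endothelial-like 6.69% and 15.9%, B-like 25.0% and 21.6%, T-like 14.2% and 14.6% and hepatocyte-like 35.2% and 12.3%. These are shares of cells captured after F4/80 enrichment and dead cell removal, with 64.1% of control and 48.0% of GS-KO barcodes kept, and they are not shares of the liver.

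**Figure D2:**
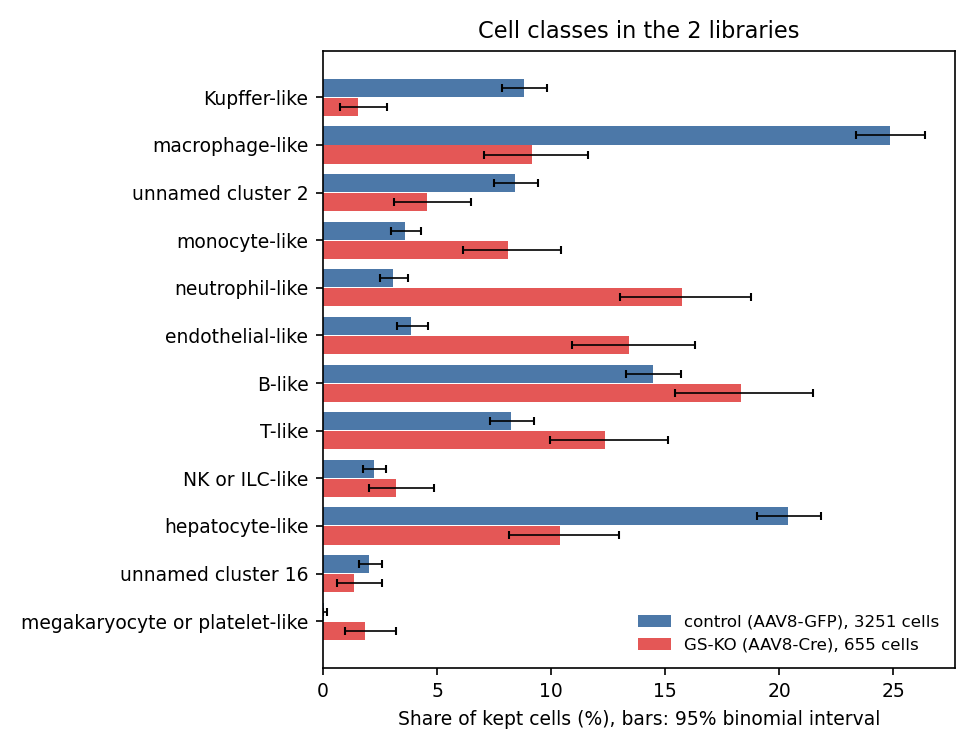
Share of kept cells (%) in each class, as bars with 95% binomial intervals, for 3251 control and 655 GS-KO cells. Kupffer-like and macrophage-like bars are longer in the control library, and neutrophil-like, endothelial-like and monocyte-like bars in the GS-KO library.

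Macrophage-like cells (808 control and 60 GS-KO) were compared to ask how the state of tumour-bearing liver macrophages differed when Glul was targeted. Interferon response genes were lower in the GS-KO library: Zbp1, a sensor of nucleic acids, had 46.2 against 13.7 CPM (3.36-fold lower). Irf7, a regulator of interferon genes, had 188 against 123 CPM and Ifi27l2a, an abundant interferon-induced gene, 1153 against 789. Of 35 measured interferon members, 9 were at least 1.5-fold lower and 1 higher, with a median log2 ratio of −0.40 (−0.53 to −0.27) at percentile 0 of random lists, and −0.17 with cells thinned to 1000 UMIs before summing. Secreted and abundant hepatocyte genes were lower in these cells too, at a median of −1.64 (−1.96 to −1.27; −1.60 with genes at 0 put at their bound) with 21 of 27 members lower, though 3346 against 3065 CPM when summed, and mitochondrially encoded genes had a median of −0.51 (−0.56 to −0.44). With these, ribosomal and haemoglobin genes left out of the total, the interferon median was −0.38. The 1 higher interferon member, Cxcl10, a chemokine, had 99.5% of its GS-KO UMIs in 1 cell. MHC class I genes, which display peptides to CD8 T cells, had a median of −0.47 (−0.64 to −0.43) with 7 of 16 members lower and 0 higher. H2-K1 had 2074 against 1247 CPM (1.66-fold lower, 1.57 to 1.76), H2-Q7 94.7 against 34.9 (2.72-fold lower) and B2m, the shared light chain, 2976 against 2116. MHC class II genes had a pooled median of −0.018 (−0.18 to 0.046; 0.0032 with genes at 0 put at their bound), with Cd74, the chaperone of class II molecules, at 13884 and 13484 CPM. Their medians differed in sign between clusters, at −0.18 (−0.23 to −0.043; −0.16 with genes at 0 put at their bound) in cluster 1, −0.48 (−0.68 to −0.29) in cluster 6 and 0.25 (0.080 to 0.48) in cluster 11.

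Lipid-associated macrophage genes, a profile of lipid-laden and scar macrophages, were also lower, with a median of −0.39 (−0.52 to −0.34) and 10 of 24 members at least 1.5-fold lower, but −0.25 as a mean over cells and −0.13 with cells thinned before summing. Gpnmb, a glycoprotein of such cells, had 328 against 102 CPM (3.20-fold lower, 2.62 to 3.96), Fabp4, a fatty acid carrier, 69.8 against 22.2, and Lpl, a lipase that frees fatty acids, 2192 against 1255. Apoe, the most abundant member, went the other way, at 41413 and 45642 CPM, a ratio of 1.10. Atp6v0d2, a proton pump subunit, had 119 against 46.5 CPM, with 52.3% of its GS-KO UMIs in 1 cell. In the lipid-rich cluster 11 alone the list median was −0.63, in cluster 1 −0.44 (−0.37 with genes at 0 put at their bound) and in cluster 6 −0.40 (−0.35). The interferon medians in clusters 1, 6 and 11 were −0.42, −0.60 and −0.31, the last −0.11 with genes at 0 put at their bound.

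Early response and heat shock genes, which rise when tissue is dissociated, were higher in GS-KO macrophage-like cells, with a median of 1.17 (1.04 to 1.23), 21 of 28 members higher and 1 lower, and 0.72 with cells thinned before summing. Hspa1b, a stress-induced chaperone, had 81.4 against 666 CPM (8.17-fold higher), Hspa1a 104 against 511 and Fos, an early transcription factor, 438 against 1767 (4.03-fold higher, 3.82 to 4.26). Dnajb1, a co-chaperone, had 36.9 against 124 CPM, Jun, the partner of Fos, 455 against 1083, and Jdp2, a repressor of Jun, 36.1 against 119. Fkbp5 and Ddit4, which are induced by glucocorticoids and stress, had 11.7 against 82.4 (7.03-fold, 5.32 to 9.23) and 8.62 against 80.3 CPM (9.31-fold, 6.92 to 12.4). Rbm3, an RNA-binding protein of cold stress, had 129 against 368 CPM and Ccdc152, of unclear function, 18.8 against 79.2. Ccl12, a monocyte-attracting chemokine, had 5.73 against 289 CPM, but 99.3% of the GS-KO UMIs lay in 1 cell and the ratio without it was 0.376.

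Genes with lower values among the named ones also included Cd209f, a lectin, at 44.2 against 3.17 CPM from 3 GS-KO UMIs, a ratio of 0.0717 (0.0147 to 0.21), and Kcnj10, a potassium channel, at 79.0 against 26.4. Cd209g, Hps6, Rusc2 and Pyroxd2 had 0 UMIs in the 60 GS-KO cells, at least 3.63-fold, 2.82-fold, 2.62-fold and 2.55-fold lower. Gm42418, which overlaps ribosomal RNA, was lower at 19382 against 8538 CPM, and Gm8797 and Gm11808, near-identical copies of other genes, were higher at 150 against 428 and 61.7 against 169, so reads of these 3 cannot be placed with certainty. Kupffer identity genes had a pooled median of 0.037 (−0.058 to 0.11), with Clec4f, a lectin of resident cells, at 3472 and 3627 CPM, but 0.17 (0.050 to 0.24) in cluster 1, −0.34 (−0.43 to −0.091) in cluster 6 and −0.79 (−0.94 to −0.44; −0.70 with genes at 0 put at their bound) in cluster 11. Haemoglobin RNA, from red blood cells, was 917 against 10.6 CPM in macrophage-like cells, but 7.18 against 21.7 in B-like and 3.61 against 32.7 in hepatocyte-like cells.

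The series title names immunosuppressive adaptation of macrophages, and a list of immunosuppressive and alternative activation markers was used for that question. In macrophage-like cells its median was −0.016 (−0.062 to 0.20) at percentile 49.5, with 4 of 22 members higher and 3 lower. By cluster the median was −0.19 (−0.31 to 0.031) in cluster 1, −0.28 (−0.74 to −0.11; −0.17 with genes at 0 put at their bound) in cluster 6 and 0.21 (−0.011 to 0.46) in cluster 11, which held 149 of the 808 control and 18 of the 60 GS-KO cells. Mrc1, a mannose receptor of alternatively activated cells, had 461 and 583 CPM (ratio 1.27, 1.16 to 1.38), Tgfb1, an immunosuppressive cytokine, 274 and 269 (0.984, 0.864 to 1.12) and Hmox1, which breaks down haem, 1193 and 1172. Clec10a, a lectin, was higher at 29.0 against 67.6 CPM (2.33-fold, 1.77 to 3.04), and Siglec1, a sialic acid receptor, lower at 68.4 against 34.9 (1.96-fold, 1.39 to 2.87). Arg1, which consumes arginine, had 13 UMIs in each library, 0.856 against 13.7 CPM, with 53.8% of the GS-KO UMIs in 1 cell. Cd274, which encodes PD-L1 and was chosen after its values were seen, had 24.4 and 18.0 CPM (0.737, 0.425 to 1.20), a difference not detectable at this depth. Inflammatory markers had a pooled median of 0.062 (−0.075 to 0.19), which joins 0.0016 (−0.30 to 0.16) in cluster 1, −0.76 (−1.22 to −0.38; −0.57 with genes at 0 put at their bound) in cluster 6 and 0.58 (0.0020 to 0.68) in cluster 11. The glutamine list, of synthesis, uptake and breakdown genes, had a median of −0.12 (−0.25 to 0.13), with Slc38a2, a glutamine transporter, higher at 42.5 against 83.5 CPM (1.97-fold, 1.54 to 2.49).

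Kupffer-like cells were 286 in the control library and 10 in the GS-KO library, so each of the 10 weighed heavily and the deepest gave 15.2% of their UMIs. Interferon genes were lower there too, with a median of −0.61 (−1.04 to −0.48), 19 of 35 members lower and 1 higher, and between −0.76 and −0.58 when any 1 GS-KO cell was left out. Iigp1, an interferon-induced GTPase, had 123 against 10.9 CPM from 2 UMIs, a ratio of 0.0881 (0.0106 to 0.319). MHC class I had a median of −0.78 (−0.99 to −0.58) with 12 of 16 members lower. MHC class II was lower here, at −0.56 (−1.12 to −0.32) with 6 of 12 members lower: Cd74 had 11550 against 4521 CPM (2.55-fold, 2.39 to 2.74), H2-Ab1 4119 against 1547 and H2-Aa 4600 against 1802, while Ifi30, a reductase of antigen processing, was higher at 1119 against 1932.

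Glycolysis genes were higher in GS-KO Kupffer-like cells at a median of 0.47 (0.25 to 0.74), 8 of 17 members higher and 2 lower, with Slc2a1, a glucose transporter, at 13.3 against 70.6 CPM (5.32-fold, 2.70 to 9.69) and Ldha, which makes lactate, at 282 against 440. Fkbp5 had 21.4 against 125 CPM (5.83-fold, 3.55 to 9.18), Rbm3 130 against 374, Noct, a clock-controlled phosphatase, 7.77 against 54.3 and Ccl24, an eosinophil-attracting chemokine, 734 against 1976 with 40.7% of the GS-KO UMIs in 1 cell. Ccl7, Ccl2, Mmp19 and Slc20a1 were higher through 1 cell that held 100%, 99.4%, 94.6% and 88.9% of their GS-KO UMIs, and Hilpda, a lipid droplet gene, had 65.5% in 1 cell. Lower genes included Rgs1, a brake on chemokine receptors, at 712 against 174 CPM (4.10-fold, 2.90 to 6.01; a log2 ratio of 0.085 at Leiden resolution 2), Fosb at 125 against 21.7 (a log2 ratio of 0.18 at resolution 0.5), and Cd209f and Cxcl13, a B cell chemokine, each with 2 GS-KO UMIs. Cd209g had 0 GS-KO UMIs (at least 2.97-fold lower), and Tmem26 and Eif3b had 1 each, with Eif3b higher, at a log2 ratio of 0.84, when cells were thinned before summing. Epb41l4aos and Serf1 were higher, at 30.9 against 114 and 30.5 against 109 CPM. The immunosuppressive list had a median of 0.032 (−0.24 to 0.31), and the early response list 0.046 with 5 of 26 members higher and 7 lower.

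Monocyte-like cells (117 control and 53 GS-KO) showed the lowest interferon medians of the macrophage lineage. Their list median was −1.44 (−1.68 to −1.08), with 27 of 31 members lower and 0 higher. Control monocyte-like cells also held more macrophage RNA, with C1q genes at 4370 against 901 CPM and Kupffer markers at 2558 against 435. The part of carried-in RNA or a different cell mix in the lower interferon and MHC values was not tested. Gbp3, an interferon-induced GTPase, had 128 against 11.6 CPM (ratio 0.0911, 0.0291 to 0.217), its relative Gbp2 137 against 34.9 and H2-Q7 112 against 23.3. Cxcl9, a T cell chemokine, had 0 GS-KO UMIs against 130 CPM in 5.98% of control cells (at least 18.5-fold lower), and Cxcl10, Cxcl13 and Ccl2 had 1, 8 and 3 GS-KO UMIs, each in 1 cell. MHC class II had a median of −0.94 (−1.47 to −0.57; −0.97 with genes at 0 put at their bound), but H2-Ab1, H2-Aa and Cd74 had 90.7%, 81.4% and 73.5% of their GS-KO UMIs in 1 cell, without which their values were lower still. Tnfsf12, a cytokine of tissue repair, had 67.3 against 6.98 CPM.

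Monocyte-derived recruitment genes were level in monocyte-like cells, at a median of −0.073 (−0.17 to 0.068) with 5 of 20 members higher and 4 lower, and members went both ways. Chil3, a chitinase-like protein of classical monocytes and of immature neutrophils, was higher in the GS-KO library, with 199 against 1459 CPM (7.32-fold, 6.28 to 8.55), Vcan, a matrix proteoglycan, 32.8 against 196 (5.96-fold, 4.02 to 8.99) and Thbs1, an adhesion protein, 17.3 against 69.8. Ly6c2, another marker of classical monocytes, chosen after its values were seen, was lower at 555 against 251 CPM. Neutrophil S100 RNA was 12.1 against 705 CPM in these cells (58.3-fold, 34.2 to 108). S100a8, part of this RNA, was seen in 7.69% of control and 13.2% of GS-KO cells, so it lay in a minority of them. GS-KO neutrophil-like cells held 141222 CPM of S100 RNA and 222 CPM of Chil3, less than the monocyte-like cells. RNA of the neutrophil-like class thus does not account for the Chil3 value, while RNA of more immature neutrophils was not tested. Kupffer identity genes had a median of −2.71 (−2.15 with genes at 0 put at their bound), with 18 of 19 members lower, as for Clec4f at 338 against 4.66 CPM. C1q RNA, which macrophages make, was 4370 against 901 CPM in these cells and 274 against 31.6 in B-like cells, but 156 against 333 in hepatocyte-like cells. Stress genes were higher, with Hspa1b at 171 against 866, Hspa1a at 177 against 756, Atf3 at 120 against 424, Dnajb1 at 37.1 against 119, Fos at 916 against 1967 and Rbm3 at 277 against 740, and Ccl3, a chemokine, had 130 against 328 (a log2 ratio of −0.020 as a mean over cells). Retnla, at 2699 against 982 CPM, and Prg4 and Pf4, at 311 against 808 and 330 against 768, came from 2 GS-KO cells each, so they describe those cells alone. The immunosuppressive list had a median of −0.39 (−0.76 to −0.24) with 3 of 19 members higher and 9 lower, but 0.36 when cells were thinned before summing.

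**Figure D3:**
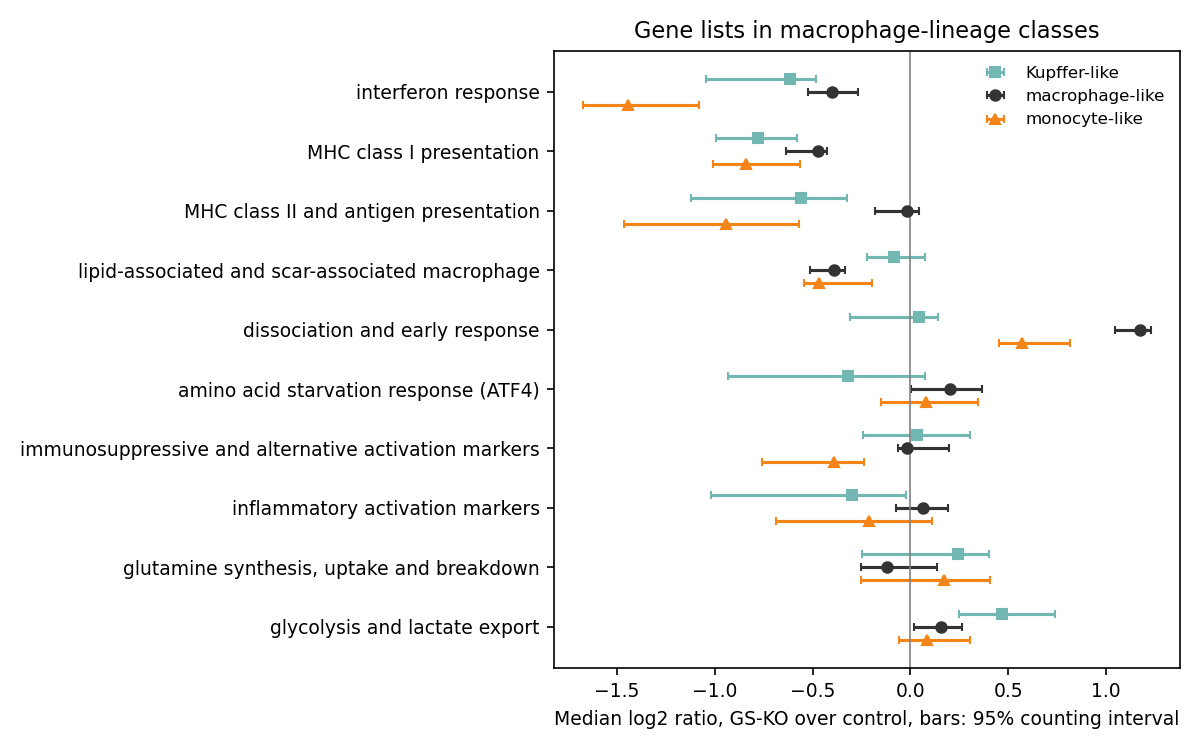
Median log2 ratio of GS-KO over control for 10 gene lists in Kupffer-like, macrophage-like and monocyte-like cells, as points with 95% counting intervals and a line at 0. Interferon and MHC class I medians lie below 0 in the 3 classes, and immunosuppressive medians lie at 0.032, −0.016 and −0.39.

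Hepatocyte-like cells were compared for zonation, since β-catenin drives the pericentral programme to which Glul belongs. The tumours were β-catenin-mutant and tumour cells were not told apart from other hepatocytes. A different mix of the 2 was therefore not separated from a shift in zonation. Pericentral and β-catenin target genes had a median of −0.90 (−1.19 to −0.68), with 14 of 24 members lower and 1 higher, and −0.53 with cells thinned before summing. Cyp1a2, a pericentral detoxifying enzyme, had 6392 against 2319 CPM (2.76-fold lower, 2.60 to 2.92), Cyp2e1, its neighbour in the zone, 2554 against 1454, Slc1a2, a glutamate transporter, 736 against 184 (4.01-fold, 3.26 to 4.98) and Lect2, a secreted β-catenin target, 725 against 200.1. Gstm3, a glutathione transferase, was an exception at 2843 and 3044 CPM. Periportal genes had a median of 1.84 (1.25 to 2.13), with 13 of 17 members higher and 0 lower. Ass1 and Arg1, enzymes of the urea cycle, had 140 against 1149 (8.20-fold, 7.49 to 8.97) and 25.0 against 298 CPM (11.9-fold, 9.90 to 14.3), and Pck1, of glucose synthesis, 18.7 against 282 with 45.7% of the GS-KO UMIs in 1 cell.

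The control class took most of its UMIs from cluster 4 (287 cells, 8 in the GS-KO library) and the GS-KO cells were mostly in the shallow cluster 5 (53 cells, 204 in the control library). Within cluster 4 the pericentral median was −1.16 (−1.01 with genes at 0 put at their bound) and the periportal median 1.67, and within cluster 5 they were −0.44 and 0.38. The deepest of the 8 GS-KO cells of cluster 4 held 82324 of its 226625 UMIs, and leaving out any 1 of the 8 gave periportal medians from 0.67 to 2.28. In the small Mup-rich cluster 15 (69 and 6 cells) the pericentral median was 0.27 (−0.32 to 0.45), with 4 of 13 members higher and 4 lower, and the periportal median 0.90 (0.34 to 1.00). As a mean over cells the periportal median was 0.26, and 1 GS-KO cell gave 16.8% of the class's UMIs. Amino acid starvation genes, targets of the stress factor ATF4, had a median of 0.56 (0.30 to 0.79) with 13 of 26 members higher and 3 lower, as for Atf5, a factor of that response, at 101 against 333 CPM (3.30-fold, 2.80 to 3.87). Their median was 0.42 in cluster 4 and 0.92 in cluster 5 (0.93 with genes at 0 put at their bound), but 0.14 at Leiden resolution 2 and 0.19 with cells thinned before summing. Cell cycle genes had a median of −1.63 (−1.49 with genes at 0 put at their bound), and 103 control cells but 1 GS-KO cell lay in the dividing cluster 13. Cdkn3 and Hmmr, both of cell division, had 0 GS-KO UMIs (at least 8.57-fold and 6.94-fold lower). Mup1 and Mup17, urinary proteins, had 267 against 20.4 and 144 against 8.17 CPM, and Cyp2c67, a detoxifying enzyme, 1214 against 178. Higher were Apcs, a plasma pentraxin, at 59.5 against 447 CPM, Mat1a, which makes the methyl donor of the cell, at 58.4 against 376, Eif4ebp3, a brake on translation, at 49.9 against 323, and Cyp4a10 and the cell cycle inhibitor Cdkn1a, with 56.2% and 84.0% of their GS-KO UMIs in 1 cell.

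**Figure D4:**
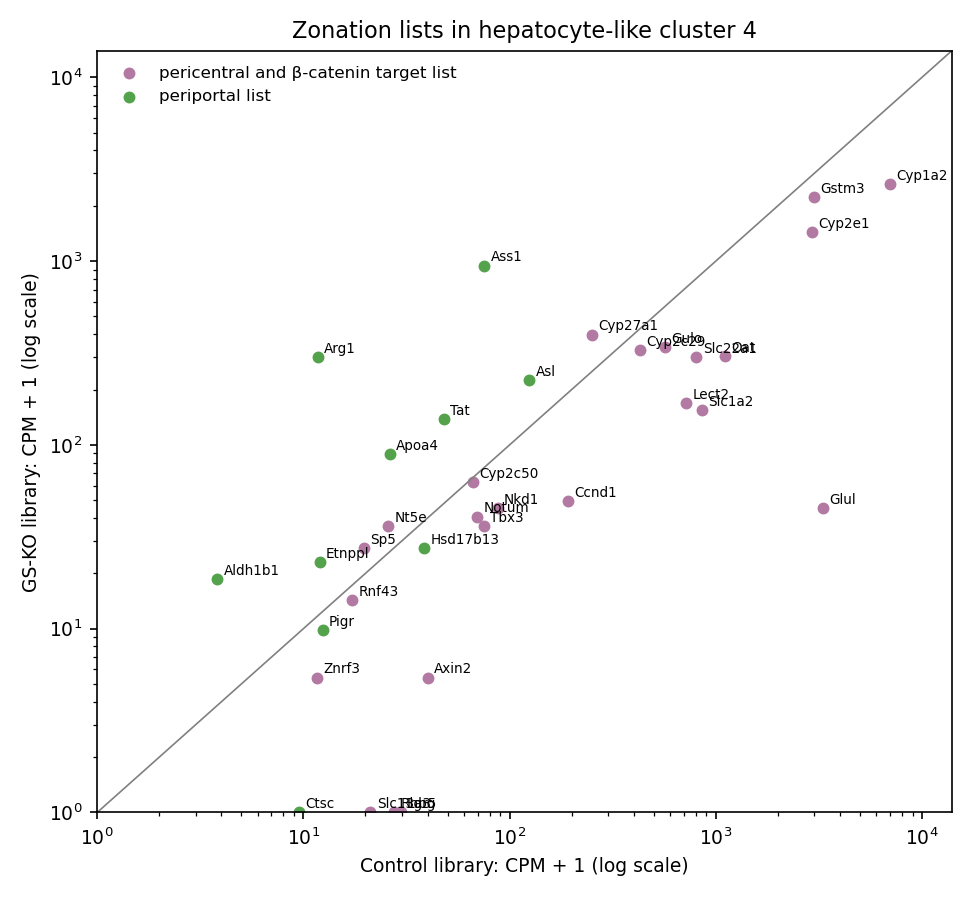
CPM plus 1 in the GS-KO library against the control library (log scales) for zonation genes with at least 50 UMIs in hepatocyte-like cluster 4, with a line of equality. Of 24 pericentral genes 21 lie below the line, and of 10 periportal genes 7 lie above it.

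Lymphocytes were compared for the same lists. Interferon genes were lower in GS-KO B-like cells, at a median of −0.96 (−1.29 to −0.45) with 11 of 16 members lower and 0 higher, as for Ifi27l2a at 576 against 237 CPM. Hspa1b was higher in B-like cells at 69.1 against 844 CPM and Hspa1a at 53.6 against 551, and Slpi, a protease inhibitor, had 13.8 against 2678 CPM through 1 cell, with a ratio of 5.29 without it. Il4i1, an amino acid oxidase, was lower at 68.0 against 17.8 CPM. Control B-like cells carried more RNA of other cells, with abundant hepatocyte genes at 1997 against 192 CPM and Kupffer markers at 212 against 23.7. In T-like cells, pooled over clusters 7 and 12, these were 1133 against 535 and 95.4 against 21.7, which need not hold in each cluster. The part of such RNA in these lower values was not tested. T-like cells had an interferon median of −0.81 (−1.10 to −0.45) with 15 of 26 members lower and 1 higher, but −0.42 (−0.70 to −0.033) in cluster 7 and −0.27 (−1.03 to −0.14; −0.24 with genes at 0 put at their bound) in cluster 12. Cytotoxicity genes had a median of −1.24 (−1.57 to −0.99) with 13 of 15 members lower, as for Nkg7, a granule protein of killer cells, at 1024 against 332 CPM, and Mki67, a mark of dividing cells, had 118 against 9.88. The T-like class joined cluster 7 (175 control and 63 GS-KO cells) and the cytotoxic and dividing cluster 12 (93 and 18 cells), so its medians also carry that difference in mix; the cytotoxicity median was −0.53 within cluster 7 and −0.60 within cluster 12 (−0.55 and −0.61 with genes at 0 put at their bound).

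Endothelial-like cells had higher hypoxia genes in the GS-KO library, with a median of 0.81 (0.52 to 1.17), 10 of 15 members higher and 0 lower. Adm, a vessel-dilating peptide induced by low oxygen, had 65.9 against 333 CPM (5.05-fold, 3.73 to 6.95), Edn1, a vessel-constricting peptide, 4.88 against 163 (33.5-fold, 12.7 to 125) and Depp1, a stress gene of the FOXO pathway, 124 against 933 (7.49-fold, 6.06 to 9.34). Early response genes were higher at a median of 1.26 (1.14 to 1.44), with Fos at 322 against 1655 CPM. Ptgs1, which makes prostaglandins, was lower at 199 against 49.2 CPM, while Mgp, Sema3g and Tmem252 had 93.2%, 98.8% and 74.4% of their GS-KO UMIs in 1 cell. Cd74 had 3621 against 162 CPM and Clec4f 1351 against 96.8 in these cells, so control endothelial-like cells carried far more macrophage RNA. Interferon genes had a median of −0.30 (−0.47 to −0.093) with 7 of 30 members lower and 1 higher.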

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

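The dilution test below was chosen after the shares had been seen, and the other tests here were chosen before their results.

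C1q genes, made by macrophages, were used to ask where the missing GS-KO macrophages could have gone. In the GS-KO library 50.8% of barcodes exceeded 20% mitochondrial UMIs, against 35.5% in the control library, and such barcodes were left out of the main shares and all gene ratios of the report. The test asked whether the excluded GS-KO barcodes held at least as much C1q RNA as the control ones. Their C1q level was 1595 against 2389 CPM of non-mitochondrial UMIs, a ratio of 0.668 (0.616 to 0.723), and filling the gap of 227 macrophages would need 7322.5 CPM. Barcodes at or under the limit already had a ratio of 0.644 (0.636 to 0.652), so a ratio of 1 was too much to ask. The needed level also assumes that lost macrophages kept the C1q share of kept ones. C1q therefore does not decide whether the limit contributed to the share of 10.7% against 33.7%. With limits of 50% and 80%, chosen after the data were seen, the share stayed lower, at 8.92% against 30.3% and 10.1% against 32.8%.

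A weaker F4/80 enrichment alone was assumed to raise every other class by a like factor. Neutrophil-like cells had a 5.11-fold higher share in the GS-KO library and B-like cells a 1.27-fold higher one, a quotient of 4.03 (3.03 to 5.37). These were the largest and smallest rises among the classes compared, picked after the shares were seen, so the quotient does not decide on dilution. Among cells other than the macrophage-lineage clusters, B-like (25.0% and 21.6%) and T-like shares (14.2% and 14.6%) stayed close. Endothelial-like (6.69% and 15.9%) and hepatocyte-like shares (35.2% and 12.3%) did not. A single factor thus did not describe all classes, but the part of weaker enrichment stays open. Loss of macrophages before capture, a different inflow of neutrophils and an effect of Glul loss in hepatocytes stay open, and with 1 mouse per group they were not tested. A separate preparation of each liver coincides with the groups.

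Zbp1, Irf7 and other interferon genes were lower in GS-KO macrophage-like cells, while Fos and Hspa1b were higher, so stress during handling could have altered both. Against 79 control macrophage-like cells with equal early response RNA (14065 CPM, against 14056 in GS-KO cells and 6633 in all control cells), which were shallower, at a median of 11299 against 16816 UMIs, the interferon median was still −0.29 (−0.51 to −0.22), compared with −0.40 against all control cells. Matching on early response RNA thus left part of the difference. Cluster mix, depth and other stress genes were not matched, so handling stress stays open. Free RNA in the control library was the other technical candidate. The interferon UMIs missing per GS-KO cell, 14.4, were 9.85 times (8.37 to 11.2) a limit of 1.46, and 27 of 27 lower members exceeded theirs. The limit took each gene's lowest mean per cell over the control classes, as if all cells carried equal free RNA. Alb, a hepatocyte gene, was in 78.8% of macrophage-like and 47.9% of B-like control cells, but in 14.7% and 16.7% at 1000 UMIs. Carried-in RNA thus rose with depth, so the limit may be too low for macrophage-like cells. Free RNA stays open. The median was −0.17 with all cells thinned to 1000 UMIs before summing. The minimum count per member was applied again after thinning, so members with few UMIs dropped out. Depth and this change of members were not separated, so depth stays open in part. An effect of Glul loss, and an infection, housing or sampling difference between 2 single mice, stay open too and were not tested.

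Platelet-like cells, marked by Ppbp, were 1.83% (0.950 to 3.18) of GS-KO cells, 12 of 655, against 1 of 3251 control cells. They form a cluster almost wholly of 1 library that no comparison of the report uses, and no explanation was tested.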

How the results depend on the processing

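No paired analysis was possible because each group has 1 mouse, and the alternatives on single GS-KO cells, single hepatocyte-like clusters, equal cluster weights, summed macrophage clusters and mitochondrial limits of 50% and 80% were chosen after the data were seen. Glul in hepatocyte-like cells stayed below control under every alternative run, at a log2 ratio between −6.23 and −3.85 against −4.61. Over 15 alternatives on macrophage-like cells as a class, the interferon median ranged from −0.51 to −0.17, MHC class I from −0.61 to −0.45, lipid-associated genes from −0.49 to −0.13 and immunosuppressive markers from −0.087 to 0.18. Its single clusters lay partly outside, at −0.60 to −0.31, −0.72 to −0.38, −0.63 to −0.40 and −0.28 to 0.21, and leaving out each GS-KO cell in turn gave interferon medians from −0.53 and lipid-associated ones from −0.50. Pericentral medians of hepatocyte-like cells ranged from −1.23 to −0.44 and periportal ones from 0.26 to 2.69 over 14 alternatives, while cluster 15, not among them, had a pericentral median of 0.27. Of 72 share differences, 56 stayed within counting error of the reported value, 16 moved and 0 reversed. Of 1619 list medians, 1364 stayed, 237 moved and 18 reversed, and of 795 values of named genes, 617 stayed, 163 moved and 15 reversed. A value counted as reversed only if its sign changed and the interval of the reported value left out 0. Other sign changes are among the values that stayed or moved. Depth limits these statements most in Kupffer-like cells, with 10 GS-KO cells. With a minimum of 20 UMIs per gene, 21 of the 24 genes named in Kupffer-like, 22 in macrophage-like and 18 in monocyte-like cells were shared, and with no minimum 17, 17 and 15. Every reversal follows by alternative, with the moved values of the share differences, of Glul and of the list medians on which the main comparisons rest. The other moved values are given only as these counts. Shares are in percentage points and the rest are log2 ratios, and the cause was not tested.

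With at most 10% mitochondrial UMIs, the share difference was −28.1 for Kupffer-like and macrophage-like cells together, −9.74 for Kupffer-like and −18.3 for macrophage-like cells. The lipid-associated median in macrophage-like cells was −0.33. In Kupffer-like cells mitochondrially encoded genes reversed to 0.13, Ccl2 to −1.73, Mmp19 to −0.48 and Slc20a1 to −0.24. With at most 50% and 80%, run for the shares alone, the difference was −11.97 and −10.6 for Kupffer-like and −9.44 and −12.1 for macrophage-like cells. With at least 1000 UMIs, mitochondrially encoded genes in Kupffer-like cells reversed to 0.016, and the interferon median in macrophage-like cells was −0.22.

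With called doublets kept, the share differences were −27.2 together, −15.4 for Kupffer-like and −11.8 for macrophage-like cells, and Fosb in Kupffer-like cells reversed to 0.000727. At Leiden resolution 0.5 they were −26.4, −16.8 and −9.62, and Fosb reversed to 0.18. At resolution 2 the Kupffer-like difference was −9.36. In macrophage-like cells the lipid-associated median was −0.32, interferon −0.26, early response 1.34 and Glul −0.38, and oxidative phosphorylation reversed to −0.046. In hepatocyte-like cells ATF4 targets were 0.14, pericentral genes −1.23, periportal genes 2.69 and Glul −6.00, and secreted hepatocyte genes reversed to 0.24; Rgs1 in Kupffer-like cells reversed to 0.085. With clustering of thinned cells, the differences were −28.3 together and −21.3 for macrophage-like cells.

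As a mean over cells, macrophage-like medians were −0.25 for lipid-associated and 0.86 for early response genes, Glul was −0.31 and ATF4 targets reversed to −0.067. Hepatocyte-like values were −0.61 for pericentral and 0.26 for periportal genes and −4.02 for Glul, and mitochondrially encoded genes reversed to −0.16. Ccl3 in monocyte-like cells reversed to −0.020.

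With cells thinned to 1000 UMIs before summing, list members with few UMIs dropped out, so these medians differ from the reported ones in members as well as in depth. Macrophage-like medians were −0.13 for lipid-associated, −0.17 for interferon and 0.72 for early response genes, and lysosome and pericentral genes reversed to 0.046 and 0.027. In Kupffer-like cells inflammatory markers reversed to 0.54, oxidative phosphorylation to −0.10, pericentral genes to 0.083 and Eif3b to 0.84. In monocyte-like cells immunosuppressive markers reversed to 0.36, NRF2 targets to 0.10 and chemokines to 0.19. In hepatocyte-like cells ATF4 targets were 0.19, pericentral genes −0.53, periportal genes 0.92 and Glul −3.90, and mitochondrially encoded genes reversed to −0.056.

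Without the GS-KO cell richest in the gene, Ccl2 and Mmp19 in Kupffer-like cells reversed to −2.33 and −0.057, Ccl12 in macrophage-like cells to −1.41, and Prg4 and Pf4 in monocyte-like cells to −0.14 and −0.69. Without the deepest GS-KO cell of each class, Prg4 and Pf4 again reversed to −0.14 and −0.69, and mitochondrially encoded genes in hepatocyte-like cells to −0.080. With clusters 1, 6 and 11 weighted equally, immunosuppressive markers were −0.087 and chemokines reversed to −0.067. With clusters 1, 2, 3, 6 and 11 summed, lipid-associated genes were −0.32 and early response genes 1.02. Hepatocyte-like cluster 4 alone gave −6.23 for Glul. Cluster 5 alone gave −3.85 for Glul, 0.92 for ATF4 targets, −0.44 for pericentral and 0.38 for periportal genes, and mitochondrially encoded genes reversed to −0.30.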

Other observations

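The glucocorticoid test below and the genes of cluster 16 were chosen after their results had been seen.

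Neutrophil-like cells (100 control and 103 GS-KO) were richer in hypoxia, glycolysis and inflammatory RNA in the GS-KO library. Hypoxia genes had a median log2 ratio of 0.96 (0.47 to 1.45; 1.01 with genes at 0 put at their bound), with 7 of 11 members higher and 0 lower, and glycolysis genes 0.75 (0.43 to 0.89), with 8 of 14 higher and 0 lower. The inflammatory list had a median of 0.62 (0.16 to 0.86; 0.65 with genes at 0 put at their bound), with 8 of 15 higher and 2 lower. Ldha, which makes lactate, had 159 against 386 CPM and Vegfa, a vessel growth factor, 11.7 against 96.6. Il1b, an inflammatory cytokine, had 7428 against 12932 CPM (1.74-fold higher), Cxcl2, which attracts neutrophils, 976 against 3696 (3.79-fold, 3.30 to 4.36) and Ccl3, which attracts monocytes, 128 against 628. Oxidative phosphorylation genes had a median of −0.41 with 25 of 57 members lower, and lysosome genes −0.57 with 9 of 19 lower. C1q RNA of macrophages (369 against 22.5 CPM) and abundant hepatocyte genes (6060 against 3155 CPM) were lower in these cells too, and their part in the lower lists was not tested. Rtp4 and Ifi27l2a, both induced by interferon, had 338 against 113 and 1831 against 885 CPM, while the interferon list median was 0.19 (−0.15 to 0.70). Camp, Ngp and Ltf, granule genes of immature neutrophils, were higher mainly through 1 cell, with 93.6%, 82.8% and 96.4% of their GS-KO UMIs.

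Elane, Prtn3, Mpo and Ctsg, which neutrophil precursors of the bone marrow express, had 6861, 3666, 1805 and 1124 CPM in the 9 GS-KO cells of the unnamed dividing cluster 16, from 4 cells each, and 0 UMIs in its 66 control cells. C1qa and Clec4f, of macrophages, had 7006 and 3258 CPM in the control cells and 118 and 0 in the GS-KO cells. C1qa was seen in 3 of the 9 GS-KO cells and in 66 of 66 control cells, so the cluster held different cells in each library and its sizes were not compared. Neutrophil S100a8 and S100a9 RNA also lay in the barcodes over the mitochondrial limit, at 1435 CPM in the control and 12042 in the GS-KO library.

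Fkbp5 and Ddit4 were higher in GS-KO macrophage-like cells, and a candidate explanation is a stronger glucocorticoid response in that mouse or its cells. The other target genes had a median log2 ratio of 0.68 (0.32 to 0.77) in macrophage-like cells, at percentile 100 of random lists, with 8 of 13 measured members at least 1.5-fold higher and 1 lower. Tsc22d3, an anti-inflammatory mediator of glucocorticoids, had 98.4 against 180 CPM, Klf9, a hormone-induced transcription factor, 21.7 against 41.2 and Cd163, a haemoglobin scavenger, 37.4 against 59.2, while Tgm2, a crosslinking enzyme, was lower at 220 against 129. Endothelial-like cells had a median of 0.59 (0.085 to 0.86), but Kupffer-like cells −0.29 (−0.93 to 0.26). The direction of macrophage-like cells fits this hypothesis, which was not set against other stress signals.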
